A study of Mus musculus with 9 samples.

How the data were processed

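The starting point was the deposited count matrices of 4 RNA libraries and 1 ATAC library from 9 samples, as each RNA library and its antibody tags were listed as separate samples. Per the labels' protocols, synovial tissue was made into a cell suspension, live cells were sorted, and libraries were prepared with droplet kits for RNA with antibody tags and for accessible chromatin. Per the submitters' processing notes, reads were processed with Cell Ranger 6 for RNA and antibody tags and with Cell Ranger ATAC 1.1.0 for chromatin, on mm10. Per the file headers, the RNA matrices hold integer UMI counts for 31053 genes and 80 antibodies, and the barcodes had already been filtered. The ATAC matrix holds counts per peak and barcode. Of its nonzero values 93.5% were even, as when both ends of a fragment are counted. The number of mice per library and any correction for free RNA are not given in the sources used here. Raw reads were not used here.

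The gene lists, markers, groups, named-gene rule and 72 alternatives were chosen before the data were examined. A further 5 alternatives and the scoring rule that names clusters were set after seeing the data.

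A barcode was kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. Scrublet scores were computed per library. Its own threshold called 29, 0, 0 and 1 doublets in the untreated MHCII-, untreated MHCII+, untreated CD64+ and day 7 libraries. The call was used for the first of these. In the others, where it reached less than 0.5% of barcodes, the highest scores were removed at 0.8% per 1000 barcodes. Of barcodes passing the filter this took out 27, 597, 670 and 815. The alternative without a cell filter still had these doublets removed. Genes seen in neutrophils or red cells were not removed from the counts, and no correction for free RNA was applied.

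Kept cells of the 4 RNA libraries were clustered together without integration. Counts were scaled per cell and log transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 were used, with 0.5 and 2.0 as alternatives. Each cluster was scored against 22 marker lists. A marker counted when it reached 50 CPM in the summed cluster and 2-fold the median cluster. A cluster took a name when at least 50% and at least 3 of the markers counted. In addition, either 3 of them had to be among its top 10 genes, more than for any other list, or the list had to lead the next by 30 percentage points. Clusters led by cell cycle genes were called proliferating, and all others stayed unnamed. Cells in clusters meeting these conditions are called Ly6c+ monocyte-like, Ly6c- monocyte-like and so on.

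For each comparison, UMIs were summed over the kept cells of a library or class and scaled to CPM. The log2 ratio used a pseudocount of 5 CPM in both sums. Intervals are exact 95% Poisson intervals for sums and exact 95% Clopper-Pearson intervals for shares; they cover counting error only. Intervals of ratios carry no pseudocount, so a ratio of small counts can lie outside the printed log2 value. A gene with 0 counts was given a limit of 3 counts. With 1 library per group no p-value was computed from cells, and no count of changed genes across the transcriptome is given. Shares of cells with a UMI were also computed after thinning each cell to 5000 UMIs, which left out cells with fewer.

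The 29 gene lists were Ly6c- monocyte, Ly6c+ monocyte, macrophage, conventional DC, MHC class II presentation, MHC class I presentation, type I interferon response, NF-kB and inflammatory cytokines, chemokines, adhesion and trafficking, Fc receptors, complement, lysosome, lipid handling, glycolysis and hypoxia, oxidative phosphorylation, matrix remodelling, immediate early and dissociation, cell cycle, antioxidant and iron, osteoclast, synovial lining macrophage, interstitial synovial macrophage, neutrophil, fibroblast, T and NK cell, B cell, erythroid, and X and Y. A member was measured when it reached 20 CPM in at least 1 of both sums, and members at 2-fold or more were counted as higher or lower. The median log2 ratio of each list with at least 3 measured members was placed among 10000 random lists of the same size, drawn within 100 expression ranks of each member. Such a percentile describes the libraries compared and carries no replicate error.

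Genes are named by 1 rule. Among genes at 50 CPM or more in at least 1 of both sums, the 8 highest and 8 lowest log2 ratios were taken, leaving out mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, sex-linked, predicted and unnamed genes. To these came the 3 measured members of each list with the largest absolute log2 ratio and the gate and monocyte genes Fcgr1, H2-Ab1, Itgam, Ptprc, Ly6g, Siglecf, Ly6c2, Nr4a1, Cx3cr1 and Ccr2. For antibodies the 5 highest and 5 lowest were taken, with CD64, I-A/I-E, CD11b, Ly-6C, Ly-6G, CD43, CX3CR1, CCR2 and F4/80. The text prints a part of these; some genes and antibodies that meet the rule are not reported here, and their own values were left out of the counts of changed results under other settings.

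Antibody counts were summed in the same way and scaled to CPM of antibody counts, so a rise in an abundant antibody lowers the others. A second scaling took the median over cells of the centred log ratio. The panel held 0 isotype controls, so no background level was subtracted.

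For the ATAC library all deposited barcodes entered. Peaks were made binary, weighted by term frequency and inverse document frequency, and reduced to 30 components. Component 1 followed depth (Spearman rho 0.9985 with counts per barcode) and was left out, so components 2 to 30 and Leiden resolution 0.6 made the clusters, with 0.3 and 1.0 as alternatives. Clusters were named by a narrower form of the RNA rule, with a minimum of 20 CPM. The list always had to lead the next by 30 percentage points. Leading genes were not used, and no cluster could be called proliferating. The plan was to use promoters. The annotation used here has no strand, so peaks within 2 kb of either end of a gene were summed, with 1 kb and 5 kb as alternatives. The annotation matched 25166 of the 31053 RNA genes (81.0%) by symbol. Accessibility per gene end was compared with summed RNA by Spearman correlation across genes, without p-values.

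The comparison of sums was tested on simulated data with 200 changed genes at 2-fold and 4-fold per comparison. The counts were drawn with Poisson error only, so coverage near 95% was set by design. UMIs that gather in few cells, as seen below for Spp1, were not simulated, and the rates given here leave out that spread. The 95% intervals covered the true ratio in 94.7 to 95.9% of genes, and 2.0 to 4.5% of unchanged lists fell outside the central 95% of random lists. Because of the pseudocount, simulated 2-fold changes came out at 0.95 to 1.00 log2 and 4-fold changes at 1.90 to 1.92 log2. Within the small Ly6c- monocyte-like class 5.30% of unchanged genes passed 2-fold by counting error, against 0% in the other comparisons.

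Tools were Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, used only for TMM scaling factors.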

Results

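CD45+CD11b+Ly6G-SiglecF- myeloid cells were sorted from ankle synovium of C57Bl/6 mice and split by CD64, the high-affinity IgG receptor that marks many macrophages, and by MHC class II. Untreated mice gave a CD64-MHCII- library, a CD64-MHCII+ library and a CD64+ library, called MHCII-, MHCII+ and CD64+ here. A further library held CD64-MHCII- cells at day 7 of serum transfer arthritis (STIA), a joint inflammation induced by intravenous serum of K/BxN mice at 85 µL per 20 g of body weight. The 4 libraries were made by CITE-seq, which counts RNA molecules (UMIs) and 80 antibody tags in the same cells. A scATAC library measured open chromatin in untreated CD64-MHCII- cells. Each group had 1 library.

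Of 3529, 8753, 9914 and 10131 barcodes in the untreated MHCII-, MHCII+, CD64+ and the day 7 MHCII- library, 3154, 6753, 6187 and 8655 were kept. Kept cells had medians of 12413.5, 12790.0, 12622 and 10763 UMIs, and the libraries held 49835643, 104341745, 103549071 and 134473583 gene UMIs. Antibody UMIs were 11567131, 47120555, 44445865 and 38417725. The ATAC library held 90853478 counts in 105974 peaks over 6654 barcodes.

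Which cell classes does each gate hold, and in what shares? The untreated MHCII- gate was a mixture in which Ly6c+ monocyte-like cells made up 41.4% (39.7 to 43.1%) and Ly6c- monocyte-like cells 16.1% (14.8 to 17.4%). Neutrophil-like cells made up 21.8% (20.4 to 23.3%) of this gate although it excludes Ly6G+ cells. In the CD64+ gate 87.6% (86.8 to 88.4%) of cells were macrophage-like, while Ly6c- and Ly6c+ monocyte-like cells made up 0.0323% and 0.0970%. In the MHCII+ gate 29.3% (28.2 to 30.4%) were like type 2 conventional dendritic cells (cDC2), 1.39% like mature dendritic cells and 7.43% were proliferating, with 0.222% Ly6c- and 0.563% Ly6c+ monocyte-like cells. At day 7 the MHCII- gate was 59.7% (58.6 to 60.7%) Ly6c+ monocyte-like and 0.404% (0.282 to 0.562%) Ly6c- monocyte-like. Neutrophil-like cells were at 0.647% (0.489 to 0.839%) there, and osteoclast-like cells at 3.36% (2.99 to 3.76%) against 0.0951% in the untreated gate. Fibroblast-like cells were rare in both, 0.666% untreated and 0.393% at day 7.

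The clusters were told apart by their leading genes: Ace, Eno3 and Treml4 for Ly6c- monocyte-like cluster 5, Plac8 and Ly6c2 for Ly6c+ monocyte-like cluster 2, Elane, Camp and Fcnb for neutrophil-like cluster 0, and Mmp9, Acp5 and Ctsk for osteoclast-like cells. Cluster 2 counted 8 of 10 Ly6c+ monocyte markers but also 10 of 15 Ly6c- ones, so its name rests on 3 of its top 10 genes. Among Ly6c+ monocyte-like clusters, Ifitm1 and Saa3 led cluster 3, Ptgs2, Il1rn and Vegfa cluster 14, and Cxcl10, Rsad2 and Ifit1 cluster 13. Cd209a, Flt3 and Mgl2 led the cDC2-like cluster, Vsig4 and Sparc macrophage-like cluster 8, and Lyve1 and Aqp1 macrophage-like cluster 9.

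Unnamed clusters held 5.04% of the untreated MHCII-, 56.6% of the MHCII+, 9.91% of the CD64+ and 24.1% of the day 7 cells. In the day 7 library they were mostly cluster 20, led by Spp1, Pdpn and Cav1, with 1959 cells or 22.6% of that library. The untreated Ly6c+ monocyte-like cells were almost all cluster 2 (1270 of 1306), whereas the day 7 ones lay in clusters 3 (2626 cells), 14 (1940), 13 (353) and 2 (247 of 5166). Of cluster 3, 14 and 13 cells 99.3%, 99.6% and 94.9% came from the day 7 library, so a cell state found there cannot be told apart from a property of that library. Because the class is made of different clusters in each state, its share follows the naming rule as well as the tissue. The Ly6c- monocyte-like cells were cluster 5 in both states, with 507 untreated and 35 day 7 cells. The macrophage-like share is not compared between gates or states, because clusters 9, 10 and 15 carried a leading marker of another class. Highest-scoring doublets had been removed, and counts of cells rather than of libraries stand behind every interval, so the intervals leave out differences between mice.

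**Figure D1:**
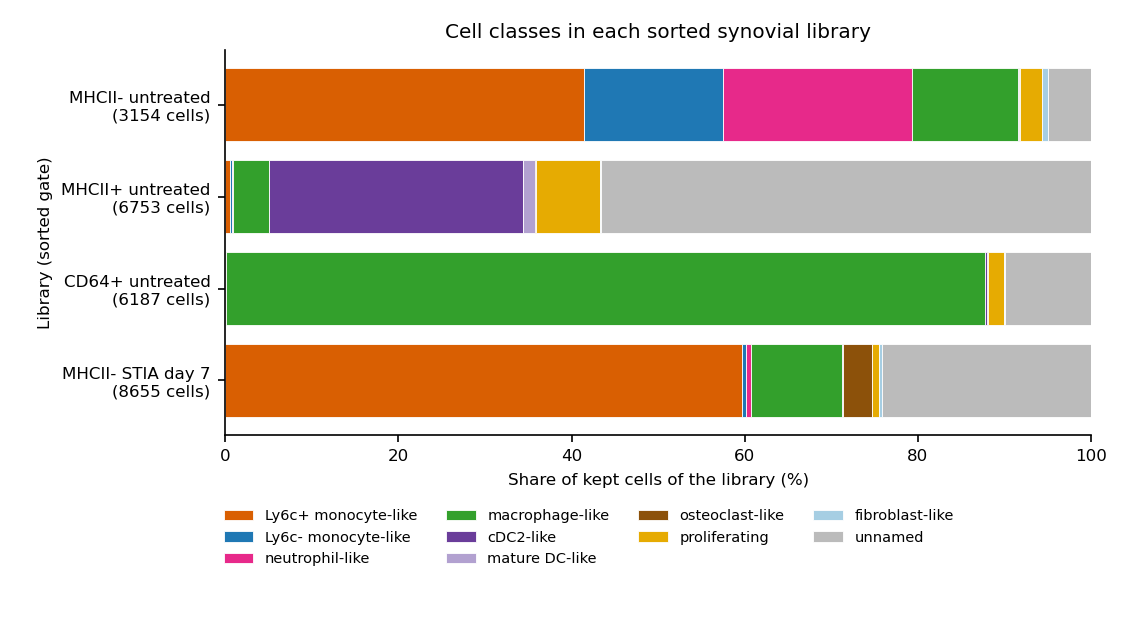
Percent of kept cells in each named class and in unnamed clusters, per RNA library. Each library is 1 bar.

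Shares of cells with at least 1 UMI of a monocyte marker gave the same order of untreated gates without clustering. C1qa, a macrophage marker, put the MHCII+ above the MHCII- gate. Ly6c2 was found in 69.2% of untreated MHCII- cells (66.7% after thinning to 5000 UMIs), 2.41% of MHCII+ (1.73%) and 0.469% of CD64+ cells (0.219%), and in 56.5% of day 7 MHCII- cells (52.5%). Macrophage-like cells of the untreated MHCII- gate, which should lack it, showed Ly6c2 in 6.19% (2.84% thinned) at a median of 12932 UMIs, against 12413.5 for the whole gate. Ace was found in 29.96% of untreated MHCII- cells (25.1% thinned), 1.496% of MHCII+ (0.978%), 0.307% of CD64+ (0.219%) and 6.39% of day 7 MHCII- cells (3.61% thinned), and in 1.29% (0.852%) of the same macrophage-like cells. C1qa was found in 99.2% of CD64+ (98.6% thinned), 32.6% of MHCII+ (26.4%) and 18.5% of untreated MHCII- cells (14.9%), while 5.05% (2.56% thinned) of the Ly6c+ monocyte-like cells of the last gate, at 11754 UMIs, had a C1qa UMI. Thinning left out 189, 923, 715 and 1535 cells of the untreated MHCII-, MHCII+, CD64+ and day 7 libraries.

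How do MHCII- cells differ in RNA from CD64+ macrophages of the same untreated tissue? Monocyte genes were higher in the MHCII- gate and macrophage, complement, chemokine and lysosome genes were lower. The Ly6c- monocyte list had a median log2 ratio of 2.70, with 13 of 14 measured members higher, and the Ly6c+ monocyte list 3.36, with 7 of 10 higher. Ly6c2 was at 900.2 CPM (892 to 909) against 0.865 (0.676 to 1.09), Ace at 109 (106 to 112) against 0.439 (0.307 to 0.607), and Itgal at 200.3 against 6.85. Plac8, Chil3 and Ccr2 had log2 ratios of 7.38, 7.25 and 1.87, and Nr4a1, which Ly6c- monocytes need, 1.56. The macrophage list had a median of -3.15 with 14 of 15 members lower, among them Mrc1 at 79.0 CPM (76.5 to 81.5) against 1042 (1036 to 1049), Cd163 (-3.15) and Folr2 (-3.48). The interstitial macrophage list (-3.03, 9 of 9 lower) and the lining macrophage list (-2.04, 4 of 6 lower) followed, with Stab1 at -4.13, Cbr2 at -4.04 and Vsig4 at 111 against 1276 CPM.

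Complement genes had a median of -2.65 (6 of 8 lower), with C1qa at 413 CPM (407 to 419) against 4021 (4007 to 4035), while C3 was higher at 4.88. Chemokines (-1.59, 9 of 12 lower; Ccl8 -3.36, Ccl24 -3.34, Ccl7 -3.26), lysosome genes (-1.26, 10 of 15 lower; Ctsd 192 against 2472 CPM, Ctsb -2.06) and matrix genes (-1.46, 7 of 13 lower and 3 higher) were lower. Also lower were MHC class II genes (-2.48, 4 of 6; H2-Ab1 97.1 CPM against 744) and conventional DC genes (-1.42, 3 of 5 lower and 1 higher), the last of which were at 0.0233 with no minimum CPM. Higher were interferon response genes (1.35, 7 of 11; Irf7 65.5 against 14.2 CPM, Ifi209 2.69), NF-kB and cytokine genes (0.75, 5 of 10; Il1b 144 against 13.9 CPM, Ptgs2 2.65) and cell cycle genes (2.23, 12 of 14; Mki67 473 against 60.6 CPM). Neutrophil genes had the largest median, 8.04 with 9 of 9 higher, led by S100a9 (10.27), S100a8 (9.99) and Camp (22207 against 17.6 CPM). Much of this RNA lay in the neutrophil-like cells, with a mean of 1556 Camp UMIs per cell against 1.03 in Ly6c+ monocyte-like cells. These cells also held most Mki67 UMIs, 19408, with 3082 in proliferating and 154 in Ly6c+ monocyte-like cells.

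Small or absent differences were seen for MHC class I (0.09, 0 of 8 at 2-fold), glycolysis (0.09, 1 of 14), oxidative phosphorylation (-0.13, 0 of 15), adhesion (0.25, 6 of 16 higher and 3 lower), lipid handling (-0.42, 4 of 9 lower), Fc receptors (-0.57, 3 of 7 lower), antioxidant and iron genes (-0.79, 4 of 10 lower) and immediate early genes (-0.60, 5 of 14 lower). The gate gene Fcgr1, which encodes CD64, was at 45.0 CPM (43.1 to 46.9) against 69.3 (67.5 to 71.2), a smaller gap than the sort by protein. Itgam and Cx3cr1 had ratios of -0.37 and -0.66, and Ptprc 1.54. Osteoclast genes (-1.73, 2 of 2 lower), fibroblast genes (0.89, 1 of 3 higher), the B cell gene Ighm (-0.25) and Xist (-0.27) were each measured in few members, and 0 erythroid genes were measured. Of T and NK cell genes Nkg7 was measured, with 2270 UMIs against 0, which allows up to 0.0365 CPM in the CD64+ gate.

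The medians of the Ly6c- monocyte, Ly6c+ monocyte, cell cycle and neutrophil lists lay above all 10000 random lists, and those of the macrophage, complement and interstitial lists lay below all. Chemokines were at percentile 0.02, interferon genes at 99.9, lysosome genes at 0.24 and adhesion genes at 90.4. The median of all genes was shifted by -0.11 in this comparison, so small list medians carry that offset. Without a second library per gate, no replicate check of any difference in these data was possible.

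**Figure D2:**
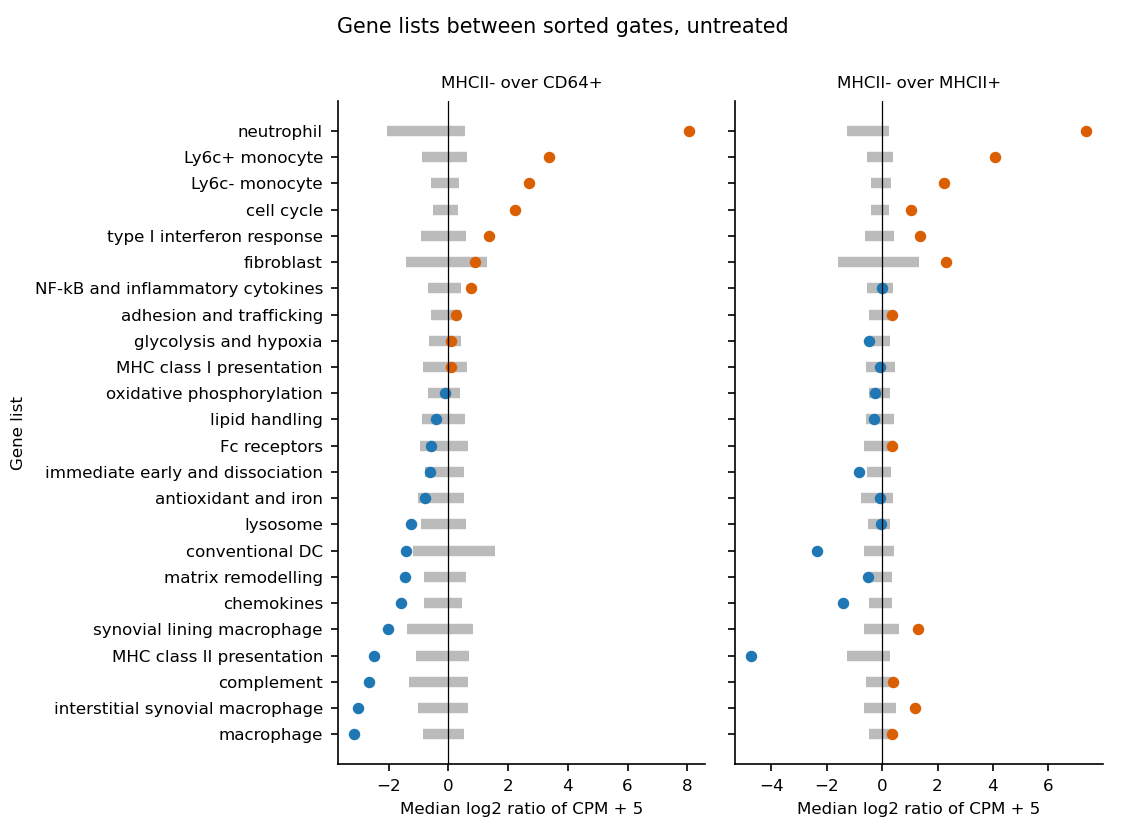
Median log2 ratio of each gene list with at least 3 measured members, untreated MHCII- over CD64+ and over MHCII+. Grey bars span the central 95% of 10000 random matched lists.

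How do MHCII- cells differ from CD64-MHCII+ cells? The gate genes and dendritic cell genes were lower, and monocyte and some tissue macrophage genes were higher in the MHCII- gate. MHC class II genes had a median of -4.72 with 8 of 8 lower, as the sort requires: H2-Ab1 was at 97.1 CPM against 9495 and Cd74 at 479 against 22268. The conventional DC list had a median of -2.34 (8 of 9 lower), with Cd209a at 3.65 against 239 CPM, Mgl2 at 22.5 against 1218 and Itgax at 10.3 against 129. Chemokines were lower (-1.41, 8 of 11), led by Ccl17 at 8.73 against 767 CPM and with Cxcl16 at -1.91, as was Retnla (325 against 6009 CPM). Ly6c- monocyte genes (2.23, 12 of 14 higher) and Ly6c+ monocyte genes (4.07, 8 of 10) were higher, with Ace at 109 against 2.80 CPM, Gngt2 at 316 against 16.0, Cx3cr1 at 283 against 29.7 and Ly6c2 at 900.2 against 7.94. Ccr2 went the other way, 758 CPM against 1472. Fcgr1 was higher in MHCII- cells, 45.0 against 5.24 CPM, although both gates are CD64-.

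Lining (1.31, 3 of 6 higher and 1 lower), interstitial (1.20, 4 of 8 higher and 3 lower) and macrophage genes (0.35, 4 of 12 higher and 2 lower) had positive medians, although the interstitial one was -0.69 with a minimum of 100 CPM, with Vsig4 at 111 against 4.27 CPM, Lyve1 at 328 against 55.1 and Apoe at 1953 against 170.5, whereas Cd163 (-2.20) and Clec10a (-2.77) were lower. Type I interferon response genes (1.38, 8 of 11; Irf7 65.5 against 7.27 CPM), cell cycle genes (1.04, 7 of 14), fibroblast genes (2.31, 3 of 3) and neutrophil genes (7.35, 9 of 9) were higher. Immediate early genes, which rise when tissue is digested, were lower (-0.83, 3 of 14; Fosb -1.78), as were matrix genes (-0.49, 4 of 12 lower and 3 higher; Mmp12 -4.14). Glycolysis genes (-0.46, 3 of 14 lower) stayed inside the central 95% of random lists. Adhesion (0.35, 6 of 17 higher), Fc receptor (0.37, 2 of 7 higher; Fcgr4 2.61) and complement genes (0.40, 3 of 8 higher; C3 4.46, Cfp -2.45) had small positive medians, and the adhesion one was -0.15 with a minimum of 100 CPM. Little difference was seen for NF-kB and cytokine genes (-0.02, 2 of 11 higher and 4 lower), MHC class I (-0.09, 0 of 8), lysosome (-0.04, 1 of 14), lipid handling (-0.29, 4 of 9 lower and 2 higher), oxidative phosphorylation (-0.27, 0 of 15) and antioxidant genes (-0.06, 2 of 9 higher). Osteoclast genes had a median of -1.504 over 2 members, and Nkg7, Ighm and Xist had ratios of 3.20, 0.74 and -0.02.

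MHC class II, conventional DC and chemokine medians lay below all random lists, and monocyte, cell cycle and neutrophil medians above all. Interstitial and lining medians were at percentiles 99.94 and 99.88, and immediate early genes at 0.04. TMM scaling moved the median of all genes to -0.11 and leaving neutrophil and erythroid genes out of the totals moved it to 0.10. Since the gates were set on MHC class II, its genes do not add to what the sort defined.

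What changes in the whole MHCII- gate by day 7 of arthritis? Matrix, osteoclast, chemokine, cytokine and glycolysis genes were higher at day 7, and Ly6c- monocyte, neutrophil, cell cycle and interstitial macrophage genes were lower. Spp1, which encodes osteopontin, was at 3592 CPM (3581 to 3603) against 12.4 (11.5 to 13.5) in untreated cells. Matrix genes had a median of 2.65 (10 of 13 higher), with Mmp14 at 204 against 3.75 CPM, Mmp9 at 467 against 17.0, Timp1 at 122 against 0.933 and Vcan at 546 against 82.9. Osteoclast genes had a median of 4.43 (5 of 5; Ctsk 1036 against 20.2 CPM, Acp5 4.71). Chemokines (1.65, 9 of 12; Cxcl2 1618 against 151 CPM, Cxcl3 3.03), NF-kB and cytokine genes (1.098, 6 of 11; Il1b 1088 against 144 CPM, Il1rn 234 against 7.55) and glycolysis genes (1.36, 11 of 15; Hif1a 582 against 97.3 CPM, Slc2a1 2.39) were higher. MHC class II genes were also higher (1.51, 7 of 7; H2-Ab1 457 against 97.1 CPM). So were lipid handling (1.08, 5 of 9; Abca1 2.01), antioxidant (0.99, 5 of 10; Hmox1 1.88) and lysosome genes (0.81, 5 of 14; Ctsl 2.79). Fibroblast genes had a median of 1.11 (3 of 5 higher; Col1a1 1.963), which was lost with cells thinned to equal UMIs (-0.0022). Fcgr1 was at 233 against 45.0 CPM in a gate sorted as CD64-, and Ccr2 at 1697 against 758.

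Ly6c- monocyte genes had a median of -1.82 (10 of 14 lower), with Ace at 11.7 against 109 CPM, Eno3 at -2.34 and S1pr5 at -2.13. Ly6c+ monocyte genes had a median of -0.52 (3 of 10 higher and 2 lower), in which Fn1 was higher (3755 against 1174 CPM) and Chil3 lower (-1.45). Without neutrophil-like cells Chil3 was at 0.54. Neutrophil genes (-4.50, 7 of 10 lower; Camp 315 against 22207 CPM, Ltf -7.26) and cell cycle genes (-2.56, 13 of 14 lower; Mki67 35.1 against 473 CPM) were lower. Interstitial (-1.66, 5 of 8 lower; Lyve1 29.7 against 328 CPM), lining (-0.84, 3 of 6; Vsig4 -2.02), macrophage (-0.62, 6 of 13 lower and 2 higher) and complement genes (-0.54, 3 of 8 lower and 3 higher) were lower. The conventional DC list had a median of -1.55 over 2 members. Little difference was seen for adhesion (0.03, 3 of 16 lower and 2 higher), MHC class I (0.30, 0 of 8), oxidative phosphorylation (0.53, 0 of 15), immediate early (0.44, 2 of 14) and Fc receptor genes (0.56, 2 of 7), each inside the central 95% of random lists. Interferon genes had a median of 0.51 (2 of 13 higher; Cxcl10 1.81) that changed sign as the mean of per-cell CPM (-0.0702), thinned (-0.0113) and without neutrophil-like cells (-0.24). Nkg7, Ighm and Xist had ratios of -2.72, -0.74 and -0.02.

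Matrix, osteoclast, chemokine, cytokine and glycolysis medians lay above all random lists and Ly6c- monocyte, neutrophil, cell cycle and interstitial medians below all. The Ly6c+ monocyte list was at percentile 0.17 and interferon genes at 99.65. TMM scaling moved the median of all genes to 0.22 in this comparison. The whole gate mixes changes in class shares with changes inside classes.

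**Figure D3:**
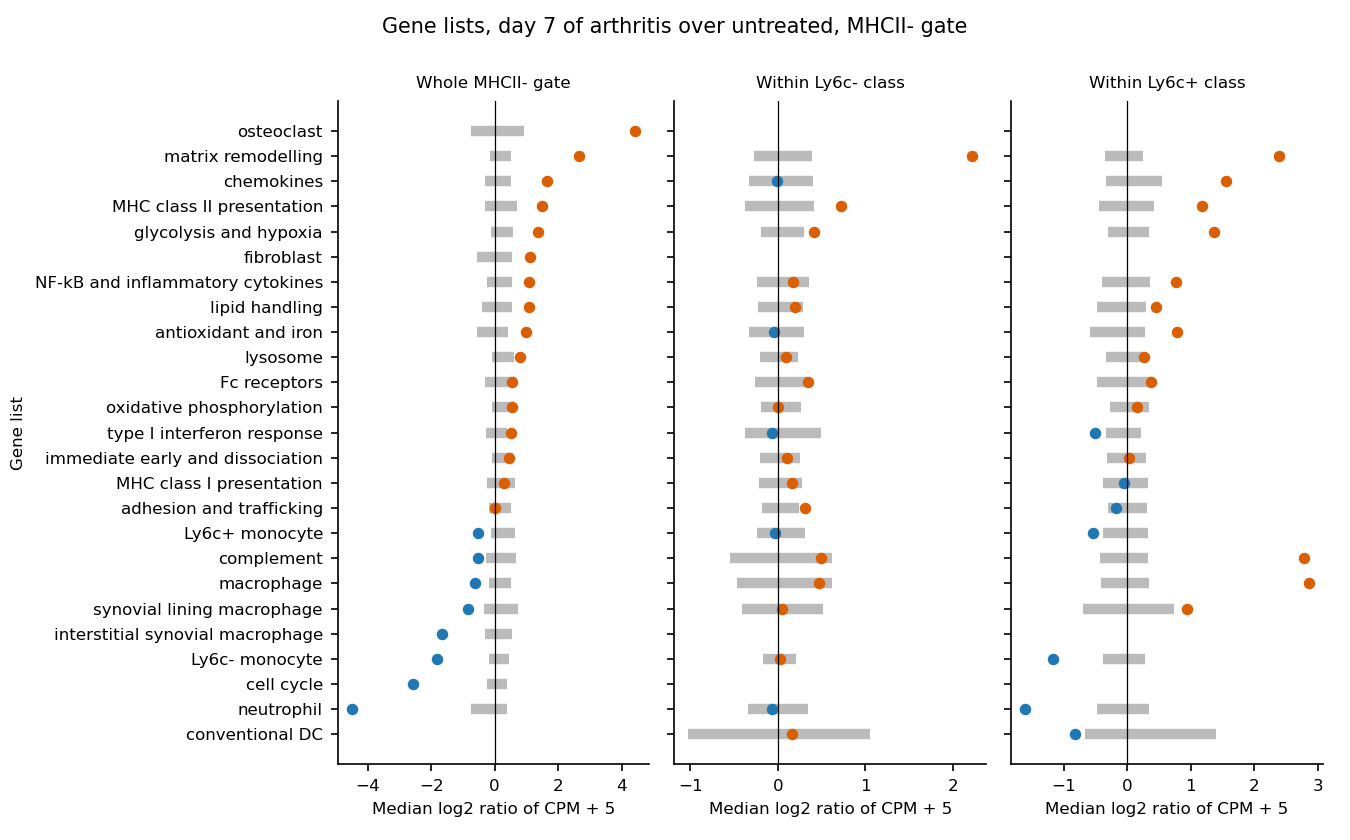
Median log2 ratio of each list, day 7 over untreated, in the whole MHCII- gate and within the Ly6c- and Ly6c+ monocyte-like classes. Grey bars span the central 95% of 10000 random matched lists.

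Do Ly6c- monocyte-like cells that remain at day 7 differ from untreated ones? With 35 cells and 198673 UMIs against 507 cells and 4203322 UMIs, 3 counts stand for 15.1 CPM at day 7 and 0.714 CPM untreated, so most genes could not be judged. The Ly6c- monocyte list hardly differed, with a median of 0.03 (0 of 15 at 2-fold), and Nr4a1 had a ratio of 0.19. Such small values were partly set by design. The list's members name the cluster, and day 7 cells were placed in it for being like untreated ones. Itgal was higher at 1489.9 CPM (1325 to 1669.6) against 957, found in 32 of the 35 cells, as were Klf2 at 1575 (1406 to 1760.0) against 811 and Fcgr4 at 544 (446 to 656) against 282. Without the 2 cells that held most UMIs of the gene in question, which lowers the day 7 side by design, Itgal was at 1376 CPM, Klf2 at 1417 and Fcgr4 at 448. Il1b was at 795 CPM (676 to 929) against 396, but 73 of its 158 UMIs lay in 2 cells, without which it was at 454. Cx3cr1 was lower, 569 CPM (469 to 684) against 926 (897 to 956). Adhesion genes had a median of 0.31 (0 of 15 at 2-fold) and MHC class II genes 0.73 (2 of 6 higher). The MHC class II UMIs sat in few cells: H2-Ab1 was at 166 CPM (114 to 233) against 62.1, with 26 of 33 UMIs in 2 cells and 38.4 CPM without them, and H2-Aa had 20 of 25 in 2 cells.

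The largest ratios belonged to Spp1, Arg1, Il1rn, Emp1, Ctsk and Fn1, and all of these but Ctsk came mainly from the same 2 cells. Spp1 had 105 UMIs against 2 in the untreated class, and on the log2 scale the 95% interval of this ratio ran from 8.23 to 13.18. Of the 105, 94 lay in 2 of the 35 cells, and without these the log2 value was 3.61 in place of 6.61. The same cells held 13 of 15 Arg1 UMIs (3 untreated, ratio interval 4.90 to 9.15), 22 of 23 Il1rn UMIs, 14 of 21 Emp1 UMIs and 112 of 145 Fn1 UMIs. Ctsk was spread over 10 cells with 13 UMIs, 65.4 CPM (34.8 to 112) against 3.57 (1.997 to 5.89), and had a log2 ratio of 3.19 without the 2 cells. It was found in 28.6% (14.6 to 46.3%) of the class, next to 18.2% of cluster 2 and 19.7% of cluster 3 cells of the same library, which also held osteoclast-like cells with a mean of 382 Ctsk UMIs, so free RNA is not excluded. Matrix genes had a median of 2.22 (5 of 9 higher), which was 0.33 without them, and glycolysis genes 0.41 (2 of 14), which was 0.22. MHC class II was at 0.85 and adhesion at 0.31 without these 2 Spp1-rich cells, which held 0 H2-Ab1 UMIs.

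Other lists within the class had medians near 0: Ly6c+ monocyte -0.03 (3 of 10 higher; Fn1 2.68), NF-kB and cytokines 0.17 (1 of 9 higher and 1 lower), interferon -0.07 (2 of 9 lower), chemokines -0.01 (1 of 6; Ccl4 1.55), MHC class I 0.16 (0 of 9), oxidative phosphorylation 0.01 (0 of 15), lysosome 0.09 (2 of 14), lipid handling 0.20 (0 of 10), immediate early 0.11 (1 of 13), antioxidant -0.04 (1 of 7 lower) and lining macrophage 0.05 (0 of 3). Fc receptor (0.35, 0 of 7), complement (0.50, 2 of 5) and macrophage lists (0.47, 1 of 5) had small positive medians. Conventional DC genes were at 0.16 (1 of 3 lower), the middle of random lists, and neutrophil genes at -0.06 (3 of 8 lower), in which Camp and Ngp rest on few cells: Camp was found in 2.86% and Ngp in 5.71% of the cells, with 18 UMIs each, against 56.6% and 48.9% untreated. Osteoclast genes had a median of 1.61 over 2 members. The interstitial list had F13a1 (1.36) and the cell cycle list 1 member (0.60); Ighm and Xist were at -0.48 and 0.28, and 0 fibroblast, T and NK cell or erythroid genes were measured. Dnmt3a, with 231 UMIs or 55.0 CPM untreated, and Retnlg, with 159 UMIs or 37.8 CPM, had 0 at day 7, which allows up to 15.1 CPM. The matrix list lay above all random lists, MHC class II at percentile 99.97, adhesion at 99.66, glycolysis at 99.8 and the NF-kB list at 82.3.

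Do Ly6c+ monocyte-like cells differ at day 7? Here the named class changed its clusters, from cluster 2 in untreated cells to clusters 3, 13 and 14 at day 7, so the class-level ratio compares cell states more than the same state. At class level macrophage genes were higher (2.86, 6 of 9), with Mrc1 at 105 against 10.2 CPM. So were complement genes (2.79, 6 of 8; C1qa 102 against 4.92 CPM, C1qb 188 against 9.85, C3ar1 194 against 9.98), matrix genes (2.40, 8 of 12; Timp1 4.17, Vcan 2.25), chemokines (1.55, 6 of 10; Cxcl2 1359 against 123 CPM) and glycolysis genes (1.37, 12 of 15; Hif1a 687 against 145 CPM). MHC class II (1.17, 6 of 7; H2-Ab1 596 against 127 CPM), NF-kB and cytokine (0.77, 4 of 11; Tnf 1.18), antioxidant (0.78, 2 of 8; Srxn1 1.60), lipid handling (0.46, 2 of 8 higher) and lining genes (0.94, 1 of 3 higher and 1 lower) were higher. Lysosome (0.27, 3 of 14) and Fc receptor genes (0.37, 2 of 7; Fcgr1 1.38) stayed inside the central 95% of random lists. Spp1 was at 1563 against 5.38 CPM, Arg1 at 198 against 0.389 and Dab2 at 266 against 8.29.

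Ly6c- monocyte genes were lower (-1.17, 7 of 12; Ace 14.2 against 89.3 CPM, Adgre4 -1.91), as were Ly6c+ monocyte genes (-0.55, 4 of 10), neutrophil genes (-1.61, 4 of 6; Camp -3.40) and conventional DC genes (-0.83, 1 of 3). Cluster 2, which held most untreated cells of this class, had itself counted 10 of 15 Ly6c- monocyte markers. Interferon genes had a median of -0.50 with 0 of 15 lower and 1 higher at 2-fold (Irf7 -0.72). In cluster 13, which such genes lead, the interferon median over untreated cluster 2 was 1.99. Itga4 was at 189 against 705 CPM, within an adhesion list at -0.17 (3 of 14 lower and 1 higher). Cx3cr1 had a ratio of -1.03, Nr4a1 -0.81 and Ccr2 0.16. MHC class I (-0.05, 0 of 9), oxidative phosphorylation (0.15, 0 of 15) and immediate early genes (0.03, 1 of 13) differed little. The interstitial list had a median of 1.31 over 2 members; the osteoclast gene Acp5 was at 0.99, the cell cycle gene at 0.66, Ighm at -1.03 and Xist at -0.02, and 0 fibroblast, T and NK cell or erythroid genes were measured. Macrophage, complement, matrix, glycolysis and MHC class II medians lay above all random lists and Ly6c- monocyte and neutrophil medians below all; the NF-kB list was at percentile 99.97. TMM scaling moved the median of all genes to 0.12.

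When the 247 day 7 cells in cluster 2 were set against the untreated cells of cluster 2, little was left: macrophage 0.13, complement 0.10, chemokines 0.18, glycolysis 0.27, matrix 0.49, Ly6c- monocyte -0.23 and Ly6c+ monocyte -0.06. NF-kB and cytokine genes (-0.12; Tnf -0.21), lipid handling (-0.0656), lining (-0.26), conventional DC (0.13) and neutrophil genes (0.11) changed sign, MHC class II was at 0.77 and interferon genes at -0.72. This alternative was added after the class-level result had been seen. Day 7 cells placed in cluster 2 are chosen for being like untreated cells, so small values were to be found there by design.

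Which day 7 cells carry Spp1? Spp1 UMIs were found in 75.3% of day 7 MHCII- cells (59.6% thinned) against 6.09% of untreated ones (2.36% thinned), 13.8% of MHCII+ (7.94%) and 13.3% of CD64+ cells (7.62%). The mean was 0.713 UMIs per cell in cluster 2, 2.84 in cluster 3, 34.7 in cluster 13, 49.98 in cluster 14 and 132.9 in the unnamed cluster 20, of which Spp1 is a leading gene. The 35 Ly6c- monocyte-like cells had a mean of 3.0 and a median of 0, with Spp1 in 25.7% (12.5 to 43.3%) at a median depth of 5445 UMIs, and in 27.8% of the 18 left after thinning. Cluster 2 cells of the same library showed it in 50.6% at 11902 UMIs. In untreated cells Spp1 was found in 0.395% of Ly6c- and 0.766% of Ly6c+ monocyte-like cells.

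**Figure D4:**
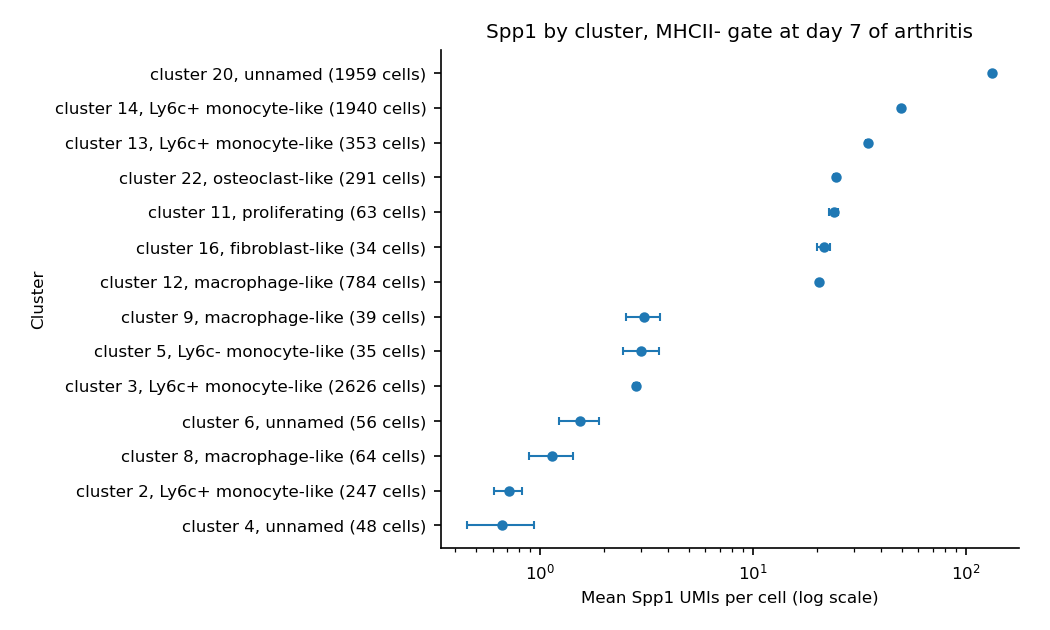
Mean Spp1 UMIs per day 7 cell in each cluster of at least 30 day 7 cells, with exact 95% Poisson intervals. The axis is logarithmic.

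Do surface proteins follow the same lines? Between gates, antibodies against gate proteins mostly followed the sort, while RNA did not match every antibody. CD106 was higher in MHCII- cells, but its gene Vcam1 was at 0.238 and 0.0648 CPM in untreated Ly6c- and Ly6c+ monocyte-like cells. CD11b was higher than in CD64+ cells, while Itgam RNA was lower. Against CD64+ cells, MHCII- cells had more Ly-6C (152293 CPM of antibody counts against 1607, log2 6.56), CD11a (5.39), CD36 (4.76), CD106 (3.94) and CD43 (3.15), and less CD204 (-6.21), I-A/I-E (-3.20), FrB (-3.07), CD163 (-2.28), Tim-4 (-2.23), CD64 (1553 against 5035, -1.69) and F4/80 (-1.38). Against MHCII+ cells they had more Ly-6C (6.14), CD36 (5.13), CD106 (4.73), CD43 (3.56) and CX3CR1 (2.17), and less I-A/I-E (-5.84), CXCR4 (-4.52), CD11c (-2.54) and CD301b (-1.91). CD64 was 2.72 higher in MHCII- than in MHCII+ cells. CD11b differed by 0.39 and 0.94 and Ly-6G against CD64+ cells by 0.19.

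At day 7 the MHCII- gate had more MAC-2, the protein of Lgals3 (31945 CPM against 2186, log2 3.87), CD14 (3.25), CD124 (2.16), CX3CR1 (1.80) and CD45 (1.73), and less CD106 (-5.59), CD357 (-3.33) and F4/80 (-1.76). Ly-6C and I-A/I-E differed by 0.22 and 0.19 and CD64 by 0.64. Within Ly6c- monocyte-like cells MAC-2 (3.80), CD14 (2.74), CD45 (1.72) and CX3CR1 (1.65) were higher, and CD106 (-3.73), CD115 (-3.54) and F4/80 (-2.85) lower. Within Ly6c+ monocyte-like cells MAC-2 (3.93), CD14 (3.46), CX3CR1 (1.46), CD86 (1.33) and I-A/I-E (1.30) were higher, and CD106 (-4.02) and CD137 (-3.59) lower. RNA did not always move with protein: Cx3cr1 RNA had ratios of -0.70 and -1.03 in these classes, and Adgre1, the gene of F4/80, 0.47 in both. In centred log ratios MAC-2, CD14, CD45 and CX3CR1 were higher at day 7 in each of 7 classes, by 2.22 to 3.15, 0.466 to 2.46, 1.09 to 2.11 and 0.585 to 1.29, and CD47 and CD106 were lower in each, with shifts of -1.55 to -0.99 and -3.42 to -0.62. Of these classes the macrophage-like, Ly6c+ monocyte-like and unnamed ones were made of different clusters in each state. Without isotype controls, a change of staining between libraries cannot be separated from a change of protein.

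Does the chromatin of the untreated MHCII- gate hold the same cell classes? Of 6654 barcodes, 322 (4.84%, 4.34 to 5.38%) formed a Ly6c- monocyte-like cluster (cluster 4) and 327 (4.91%) neutrophil-like clusters. Counts per barcode had a median of 2217 with quartiles of 909 and 26440.25, and 3684 barcodes had fewer than 3000 counts, which makes shares of all barcodes low for every named class. Unnamed clusters 1 and 2 held 29.9% and 20.3% of the barcodes, cluster 7 14.5% and cluster 3 12.4%. Gene-end accessibility of cluster 4, relative to clusters 3, 7 and 9, went best with RNA of Ly6c- monocyte-like cells (rho 0.484 over 6960 genes that are not markers). Cluster 3 went best with Ly6c+ monocyte-like RNA (0.410), cluster 7 with macrophage-like RNA (0.549) and cluster 9 with neutrophil-like RNA (0.558).

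Among genes in clusters 3, 4, 7 and 9, Ccr2 (mm10 chromosome 9, 124101918 to 124109140) had 18.4, 6.73, 1.97 and 8.61 CPM of gene-end counts. C1qa (chromosome 4, 136895916 to 136898844) had 7.68, 3.47, 130.4 and 5.37. Nr4a1 (chromosome 15, 101253902 to 101274795) was open in all, with 323, 483, 199.8 and 259; it is a marker that named cluster 4, as is Ace (chromosome 11, 105967948 to 105989964) with 43.1, 139, 8.22 and 3.81. Immediate early genes had the high medians of 170.2, 163, 155 and 123 CPM. Over 7047 genes, accessibility in the whole library correlated with RNA of the untreated MHCII- gate at rho 0.271, MHCII+ at 0.245, CD64+ at 0.229 and day 7 MHCII- at 0.2702. The correlations are descriptions across genes, and gene ends include both promoters and 3' ends.

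**Figure D5:**
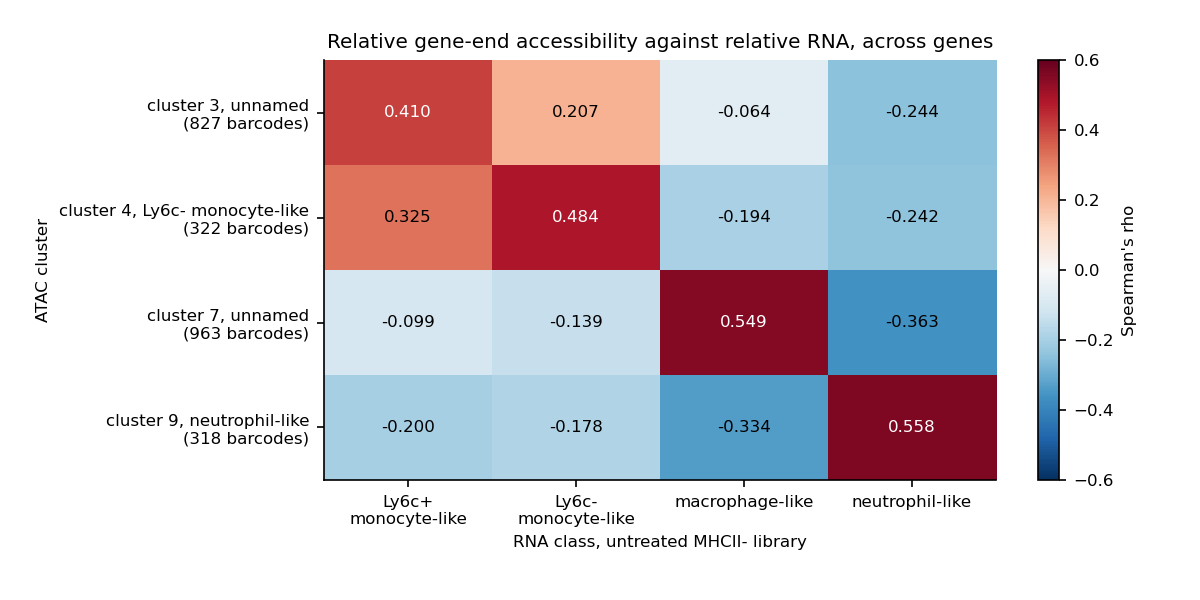
Spearman correlation across 6960 genes between gene-end accessibility of 4 ATAC clusters and expression of 4 RNA classes. Each profile was taken relative to the mean of its own 4.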

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

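Of the tests below, the one on Lgals3 RNA was written down before its values were seen; the others were chosen after seeing the result.

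The neutrophil-like share of the MHCII- gate was 33.7 times (25.6 to 45.0) as high in the untreated library as at day 7, although the gate excludes Ly6G+ cells. Free RNA taken up by other cells was excluded as the source, since neutrophil-like cells held 1505.0 times as many Camp UMIs per cell as Ly6c+ monocyte-like cells of the same library. Dilution of every other class by incoming cells to the same degree was not seen, as the fold for neutrophil-like cells was 19.9 times that of fibroblast-like cells. That reference rests on 21 untreated and 34 day 7 cells left in a CD45+ sort, which limits it as a gauge. Ly6c- monocyte-like cells had a fold of 39.8 (28.2 to 57.7), which overlaps the neutrophil-like one. Dilution as a part of the difference stays open. Bone marrow carried along at dissection may be the source of the neutrophil-like cells. Elane, a gene of marrow precursors and a leading gene of cluster 0, was at 1930.9 CPM in them. It was found in 44.1% of them, with a median of 0 UMIs per cell, while 89.8% of them had a Mki67 UMI. Whether the marrow came along in dissection or such precursors sit in the synovium stays open, and a stricter Ly6G- sort would miss precursors that have little Ly6G (845 Ly6g UMIs in the whole gate).

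In the day 7 library MAC-2, CD14, CD45 and CX3CR1 antibody counts were higher in every class compared, while others, such as CD47 (-1.55 to -0.99 in centred log ratios) and CD106 (-3.42 to -0.62), were lower in every class. For CD45 a rise in its RNA was excluded as the cause within Ly6c+ monocyte-like cells, where Ptprc had a log2 ratio of -0.74, but not in each class, as Ptprc was at 453 against 309 CPM in neutrophil-like cells. For MAC-2 the RNA left the question open, with Lgals3 at 0.60 within Ly6c- monocyte-like cells, below the 2-fold rise asked for and above 0, and at 0.27 within Ly6c+ monocyte-like cells, where MAC-2 was higher by 3.93. The smallest CD45 shift over the classes was 1.09 in centred log ratios, which could come from a difference in staining or from arthritis, because both change with the library. With 0 isotype controls in the panel, a repeat of the staining on pooled, hashed cells would be needed to tell.

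Camp and Spp1 were found inside monocyte-like classes that are not known for them. The Camp UMIs of untreated monocyte-like and macrophage-like cells are likely free RNA of the neutrophil-like cells: mean counts per cell differed by 1.3-fold at most between the other classes of at least 100 cells. Spp1 in Ly6c- monocyte-like cells at day 7 may also be free RNA, as 25.7% of them had a UMI against 50.6% of the deeper cluster 2 cells; 2 cells held 94 of the 105 UMIs, and without them the log2 ratio was 3.61 in place of 6.61. Evenly spread free RNA was excluded for clusters 13 and 14 of the Ly6c+ monocyte-like class. The smaller of their means was 42.0 times the upper bound of cluster 2. Cluster 2 had the lowest Spp1 mean among day 7 clusters of at least 100 cells. The median of cluster 13 was 2 UMIs against 1 in cluster 2, so this holds for a part of the cluster 13 cells. For cluster 3, with a mean of 2.84 and a median of 1, the question is left open. Doublets of a Ly6c- monocyte-like cell with a cell of cluster 20 stay possible for the 2 cells. Doublets with cluster 20 cells were not tested for clusters 13 and 14.

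At day 7 the adhesion and trafficking list had a median log2 ratio of 0.31 within Ly6c- monocyte-like cells and -0.17 within Ly6c+ monocyte-like cells, and the conventional DC list 0.16 and -0.83. The difference between the classes was not tested for either list. The adhesion value within Ly6c- cells was also 0.31 without the 2 Spp1-rich cells, so these cells are not its cause, and the cluster change of the Ly6c+ class could account for the other side.

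In the CD64+ library 29.0% of barcodes (2873 of 9914) were over the mitochondrial limit, against 8.98%, 14.7% and 5.07% in the untreated MHCII-, MHCII+ and day 7 libraries. They had a median of 2382 UMIs, against 12622 in kept cells, and fewer C1qa (2211 against 4021 CPM) and Lyve1 (941 against 2175 CPM) but more Mrc1 UMIs (1311 against 1042 CPM). They might be damaged macrophages of another make-up than the kept ones; without any cell filter the list median for macrophage genes in MHCII- against CD64+ cells was -3.10 in place of -3.15, and what the barcodes are was not tested.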

How the results depend on the processing

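The alternatives changed the filter, doublets, clustering, scaling, pseudocount, minimum expression, weight of cells and depth; 5 more were chosen after seeing the data. A change of sign was counted for lists outside the central 95% of random lists and for genes and antibodies at 2-fold or more. Of list medians 717 moved beyond their counting range, 13 changed sign in this sense and 635 stayed in range. The counts were 1531, 19 and 1914 for named genes, 133, 0 and 29 for antibodies, 14, 0 and 10 for class shares, and 47, 0 and 37 for ATAC values. Where a value moved, the cause was not tested unless stated. Depth limits the Ly6c- monocyte-like class most, as 3 counts there stand for 15.1 CPM at day 7. A correction for free RNA from empty droplets and a comparison over mice could not be run on the files used here.

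The untreated share of Ly6c- monocyte-like cells, 16.1%, was 13.5% without cell filter, 22.4% at resolution 2.0 and 21.3% with each library clustered on its own; at day 7 the last gave 1.02% in place of 0.404%. The Ly6c+ share depended strongly on the settings. Untreated, it was 41.4%, but 1.91% with at least 1000 genes and at most 5% mitochondrial UMIs, 2.38% at resolution 0.5, 35.0% at resolution 2.0 and 19.5% with own clustering. The first of these settings left 1202 of 1268 cells unnamed and resolution 0.5 left 1244 of 1306 unnamed, so the naming rule rather than the cells made the difference. At day 7 it was 59.7%, and 70.8% without filter, 69.0% with the stricter filter, 85.4% with doublets kept, 88.9% and 58.0% at resolutions 0.5 and 2.0 and 68.5% with own clustering.

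The macrophage list in MHCII- over CD64+ cells, at -3.15, was -3.09 with TMM factors, -3.26 with a pseudocount of 1 CPM, -3.29 with a minimum of 100 CPM, -3.03 as the mean of per-cell CPM and -2.96 with neutrophil and erythroid genes out of the totals. The conventional DC list in MHCII- over MHCII+ cells, at -2.34, was -3.02 with a pseudocount of 1 CPM, -2.28 with no minimum, -2.77 with a minimum of 100 CPM and -2.44 as the mean of per-cell CPM. The Ly6c- monocyte list at day 7 in the whole gate, at -1.82, was -1.71 with TMM factors, -2.05 with a pseudocount of 1 CPM, -1.61 with a minimum of 100 CPM, -2.34 as the mean of per-cell CPM, -2.37 thinned, -2.01 with neutrophil and erythroid genes out of the totals and -2.30 without neutrophil-like cells. The Ly6c+ monocyte list there, at -0.52, was -0.38 with TMM factors, -0.96 as the mean of per-cell CPM, -0.83 thinned, -0.72 with neutrophil and erythroid genes out of the totals and -0.44 without neutrophil-like cells. The NF-kB and cytokine list within Ly6c+ monocyte-like cells, at 0.77, was 0.98 with TMM factors, 0.67 with no minimum, 0.82 without cell filter, 0.86 as the mean of per-cell CPM, 0.84 thinned, 0.28 for cluster 3 and 1.15 for cluster 14 over untreated cluster 2. Within Ly6c- monocyte-like cells, at 0.17, it stayed in its counting range throughout, which includes 0 (-0.0671 with no minimum).

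Antibody Ly-6C in MHCII- over CD64+ cells, at 6.56, was 6.36 without cell filter and 6.41 by centred log ratio; I-A/I-E in MHCII- over MHCII+ cells, at -5.84, was -5.82 and -8.57; MAC-2 at day 7, at 3.87, was 4.16 by centred log ratio. The Ly6c- monocyte-like share of ATAC barcodes, 4.84%, was 9.76% among barcodes with 3000 counts or more and 0% at resolution 0.3, where the cluster lost its name. The correlation of accessibility and RNA, 0.271, was 0.660 with no minimum CPM, 0.210 with a minimum of 100 CPM and 0.210 over gene bodies; with RNA of the MHCII+ gate, at 0.245, these were 0.658, 0.203 and 0.184.

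These values, called in the sense above, changed sign. In MHCII- over CD64+ cells the conventional DC list was 0.0233 with no minimum. In MHCII- over MHCII+ cells the adhesion list was -0.15 and the interstitial list -0.69 with a minimum of 100 CPM. In the whole gate at day 7 the interferon list was -0.0702 as the mean of per-cell CPM, -0.0113 thinned and -0.24 without neutrophil-like cells, and the fibroblast list -0.0022 thinned. Wfdc21 and Chil3 were 0.14 and 0.54 without neutrophil-like cells, and Col3a1 -0.0147 as the mean of per-cell CPM and -0.0022 thinned. Within Ly6c- monocyte-like cells F13a1 was -1.35 and Vegfa -0.33 without cell filter, and Vegfa -0.54 without the 2 cells with most Spp1. Comparing day 7 cluster 2 with untreated cluster 2, conventional DC was 0.13, NF-kB and cytokines -0.12, lipid handling -0.0656, lining macrophage -0.26 and neutrophil 0.11. The same comparison gave Cxcl10 -1.11, Tnf -0.21, Ccl7 -0.39, Fcgr1 -0.10, C3ar1 -0.10, Abca1 -0.67, Cd36 -0.61, Bnip3 -0.24 and S100a9 0.11. Over untreated cluster 2, the interferon list was 1.99 in cluster 13, a cluster named by such genes, Cxcl10 was -0.54 in cluster 3 and -0.42 in cluster 14, and Cd36 -1.09 in cluster 3.

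Of the 16 genes with the highest and lowest ratios, 9 stayed in the whole gate at day 7 without neutrophil-like cells, 9 within Ly6c- monocyte-like cells without the 2 cells, and 5 in cluster 2 over cluster 2.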

Other observations

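Of the tests used here, the one on Lgals3 RNA (log2 0.60) was written down before its values were seen; the others were chosen after seeing the result.

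The untreated CD64-MHCII- gate carried genes of tissue macrophages that were also seen in the CD64+ gate. Clusters 8 and 9, both macrophage-like, held 145 and 199 cells of this gate, and their shares were 6.22 and 14.002 times as high in untreated as in day 7 cells. Macrophage-like cluster 12 had the opposite order, with 0.539% of untreated and 9.06% of day 7 cells. Cluster 9 also had a leading gene from another marker list. In the gate 9 of 9 interstitial and 4 of 6 lining genes were lower than in the CD64+ gate. The cells of clusters 8 and 9 may thus be a small number of macrophages with CD64 below the sorting threshold. Fcgr1 was at 45.0 against 69.3 CPM. Free RNA of macrophages spread evenly over the cells is a poor explanation. C1qa was found in 95.6% of macrophage-like cells of the gate against 5.05% of Ly6c+ monocyte-like cells at close depth. As C1qa is among the markers that named the class, a part of this gap was set by design. Doublets with macrophages were not tested. Counting cells by CD64 protein was not used here to settle it, and other settings left the macrophage list median against CD64+ between -3.29 and -2.96.

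Mki67 RNA in the untreated gate sat mostly in neutrophil-like cells, of which 89.8% had a UMI. Elane was at 1930.9 CPM in these cells and found in 44.1% of them. The lower Mki67 level at day 7 (35.1 against 473 CPM) may therefore reflect in part the lower share of these cells. Slower division of monocytes stays open, as the proliferating cluster 11, whose best list was Ly6c+ monocyte, made up 2.41% of untreated and 0.728% of day 7 cells.

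A first hypothesis is that Ly6c- monocyte-like cells are diluted or lost at the peak of arthritis. Their share was 39.8 times (28.2 to 57.7) as high in untreated cells as at day 7, and cells with Ace were at 25.1% against 3.61% after thinning, a smaller fold that includes Ly6c+ monocyte-like cells, in which Ace was also lower. Resident classes did not differ alike. The fold of macrophage-like cluster 8 was 6.22 (4.60 to 8.48) and that of macrophage-like cluster 9 was 14.002. Macrophage-like cluster 12 went the other way, with 17 cells (0.539%) in the untreated gate and 784 (9.06%) at day 7. Equal dilution of every class would not give these folds, but dilution as a part of the difference stays open. With own clustering per library the shares were 21.3% and 1.02%, which is in line with a large difference under either choice. Counting cells per joint, with intravenous labelling to tell blood from tissue, would separate loss from dilution. The neutrophil-like share had a fold of 33.7 (25.6 to 45.0), which overlaps that of the Ly6c- monocyte-like cells. Whether marrow carried along, raised above for neutrophil-like cells, also gave a part of the untreated Ly6c- monocyte-like cells was not tested.

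A second hypothesis is that Ly6c+ monocyte-like cells turn into cells with macrophage, complement and hypoxia genes at day 7. The class as a whole was at 2.86 and 2.79 for macrophage and complement genes. The complement gene C1qb had a median of 0 UMIs in day 7 cells of clusters 3, 13 and 14. It was found in 29.1%, 29.5% and 24.9% of them, against 10.1% in cluster 2. Free RNA and doublets were not tested for macrophage and complement genes. Spp1, which is in neither list, had a mean in cluster 13 of 42.0 times the upper bound of cluster 2. Free RNA spread evenly does not explain the means of clusters 13 and 14, but the median was 2 UMIs in cluster 13 and 13 in cluster 14 against 1 in cluster 2, so in cluster 13 a part of the cells carried the mean. Cluster 3, with a mean of 2.84 and a median of 1, is left open. Whether the whole class shifted or a part of it turned into other cells stays open: the values of 0.13 and 0.10 for day 7 cells in cluster 2 were bound to be small, as cells were placed there for being like untreated ones. A snapshot of 1 library cannot give direction, and labelled transfer of Ly6c+ monocytes would.

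A further hypothesis is that Ly6c- monocyte-like cells at day 7 carry more adhesion and migration genes, with Itgal and Klf2 as candidates. Itgal is also among the markers that named the class, so day 7 cells may have been placed there in part for it. Cx3cr1, another member of the adhesion list, was lower at 569 against 926 CPM. Itgal was in 32 of 35 cells, and 33 of its 296 UMIs lay in the 2 cells that held most Spp1; the adhesion list stayed at 0.31 without them and Klf2 was at 0.94. The value rests on 35 cells of 1 library, 0 of 15 list members passed 2-fold, and a sort of more such cells from several mice, with RNA and CD11a measured, would decide it. The antibodies do not support it: CD11a, the protein of Itgal, had a shift of -0.77 in centred log ratio within these cells. CD11a was also lower in Ly6c+ monocyte-like (-0.61), neutrophil-like (-0.48) and proliferating cells (-0.46). Over the 7 classes its shifts were mixed, with the highest at 1.95. The classes not named here include the macrophage-like and unnamed ones, whose clusters differ between the states, so their shifts can come from other cells. Whether the lower value in the Ly6c- class is part of a common shift thus cannot be told. Antibody shifts at day 7 may also carry a staining difference, as CD45 was higher by at least 1.09 in all classes with Ptprc RNA at -0.74 in Ly6c+ monocyte-like cells.

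Free RNA sets a floor for genes of abundant cells. Camp counts per cell differed by at most 1.3-fold among the other large classes of the untreated gate, neutrophil-like cells had 1505.0 times the level of Ly6c+ cells, and 25.7% of Ly6c- monocyte-like cells at day 7 had a Spp1 UMI. Low levels of neutrophil genes and of Spp1 inside monocyte-like classes could thus be carry-over.

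The ATAC library places a Ly6c- monocyte-like chromatin state in the untreated gate, with Nr4a1, Ace and Cd300e among the markers that named it. Its share was 4.84% of all barcodes and 9.76% of those with at least 3000 counts, so shallow barcodes may account for a part of the gap to the RNA share of 16.1%, and the rest stays open. At resolution 0.3 the cluster was not named, which leaves its share dependent on the clustering.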
